A study of Mus musculus with 9 samples.

How the data were processed

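Liver RNA of 3 fetal, 3 adult and 3 liver cancer samples had been labelled with Cy3 and hybridised to 1 array each, with 62939 spots. Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 11.0.1.1, which subtracts the background of each spot and does not scale the arrays to each other. The files also hold raw median intensity values of spot and background, deposited as measured, and a mark for spots well above background. Spots marked as outliers on an array were left out there (0.129% to 1.30% of spots), and 0 spots were saturated.

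Control spots (1439) and 15 negative control probes recognised by name (300 spots) were set aside, which left 60915 probes. Unmarked spots of a probe were averaged as log2 processed signal, and the 75th percentile of each array was subtracted. A probe was tested if it was well above background on at least 3 of the 9 arrays and had at least 2 usable arrays per group. Signal over background limits precision: 40.5% to 69.3% of probes were well above background, and the number of arrays limits the precision of every mean.

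The 3 comparisons between groups were fitted with limma 3.58.1 in R 4.3.3 over all 9 arrays, with 1 mean per group and moderated variances. P-values were adjusted by Benjamini-Hochberg over the tested probes of a comparison. A probe was called at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. Control probes were compared with exact permutation tests, two-sided, which cannot go below p = 0.1 with 3 arrays against 3. Files were read with the R package data.table (version 1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

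The rule for naming genes was fixed before the data were examined: the strongest changes with separate groups and a gene symbol, a list of known liver and oncofetal genes, and for non-coding probes the 5 highest and 5 lowest. Only 15 probes carried a gene accession, all of which matched a symbol, so all 15 are given whether called or not, a choice made after the names were seen. The genes that were always to be named, among them Afp and H19, could not be identified. For the same reason none of the 39 gene lists had 5 members with a named probe, no list was tested, and the planned set tests and the alternative probe of a gene were not run. Probe sequences were not used here, so signal from near-identical gene copies was not separated. For a group below background on all its arrays, signals were raised to the lowest signal well above background on each array and the fold given as a lower bound. Such a bound holds for the processed signals alone: with normexp the differences of the probes given here were smaller.

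Scan was taken from the file headers. Since the second scan holds liver cancer arrays alone, a block for scan takes liver cancer differences from replicate 1, as the fits within the first scan do, and differs from them in its estimate of the spread. Alternatives comprised other scalings (quantile, array median, 75th percentile of probes above background everywhere), filters, a signal floor, blocks for scan and for replicate number, other variance models and thresholds, fits of 2 groups only, and leaving out each array in turn. The planned normexp correction needed a mean signal that the files lack. It was run on median signals (offset 50), and this and the fits within the first scan were added after the data were seen. The offset is large beside median processed signals of 11.7 to 27.3 in the first scan and 71.6 and 67.0 in the second. It shrinks fold changes of dim probes, and not equally in the 2 scans. A smaller difference or a lost call with normexp therefore does not show that a change was absent.

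The procedure was tested on simulated data with 34103 probes, of which 200 were changed. At 2-fold, 4-fold and 8-fold it called 19.4%, 67.2% and 92.4% of changed probes for liver cancer against adult liver. The shares were 13.4%, 58.2% and 78.8% for fetal against adult liver, and 17.9%, 53.7% and 84.8% for liver cancer against fetal liver. Unchanged probes were called in 0.274%, 0.0413% and 0.274% of cases, or 93, 14 and 93 probes. Changed probes called at 2-fold, 4-fold and 8-fold numbered 13, 45 and 61 for liver cancer against adult liver. The numbers were 9, 39 and 52 for fetal against adult liver, and 12, 36 and 56 for liver cancer against fetal liver. False calls were thus a larger share of all calls than the adjusted p threshold allows for. Far more probes were called in the measured data than the 200 changed here, so the simulated shares need not carry over. Sharing of the adult arrays was examined with 20 simulations of unchanged groups.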

Results

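RNA from 9 mouse liver samples was measured on 1-colour Agilent arrays for lncRNAs (long non-coding RNAs) and protein-coding RNAs, with 1 array per sample. The samples fell into 3 groups of 3: livers of embryos at day 17.5, livers of adult males aged 2 months, and liver tumours of males aged 1 year. The tumours had been induced with DEN (diethylnitrosamine, a liver carcinogen). The stated purpose was to find oncofetal transcripts, meaning RNAs shared by the fetal organ and the tumour. Age, exposure to DEN and tumour tissue differ together between liver cancer and adult liver, and the sex of the embryos is not given. The samples of a group are described as independent, without naming animals or litters, so p-values measure the spread between these samples only.

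Of 60915 probes, 15 carried a RefSeq accession and could be named, and each of these was spotted 20 times. They represent Tfrc, Tuba1b, Actb, Tbp, Hsp90ab1, Rpl13a, G6pd2, Nono, Hprt, Gusb, Ppia, Gapdh, B2m, Ldhal6b and Gk. A further 1836 probes had lincRNA names (long intergenic non-coding RNA), and 59064 had identifiers of the array maker with no gene name. In all, 34103 probes (56.0%) were tested, of which 519 had lincRNA names (28.3% of those on the array).

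The arrays came from 2 scans. The 3 fetal arrays, the 3 adult arrays and liver cancer replicate 1 shared the first scan, and liver cancer replicates 2 and 3 made up the second. Probes well above background amounted to 46.1%, 54.8% and 47.3% on the fetal arrays and to 40.5%, 42.8% and 41.9% on the adult arrays. Liver cancer replicate 1 had 42.9%, against 69.3% and 67.8% on replicates 2 and 3. The median SD between arrays of a group was 0.199 log2 in fetal liver, 0.205 in adult liver and 0.469 in liver cancer. For comparisons with liver cancer, the numbers of called probes and the named genes are therefore also given within the first scan, where liver cancer is 1 array that is assumed to vary like the others.

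**Figure D1:**
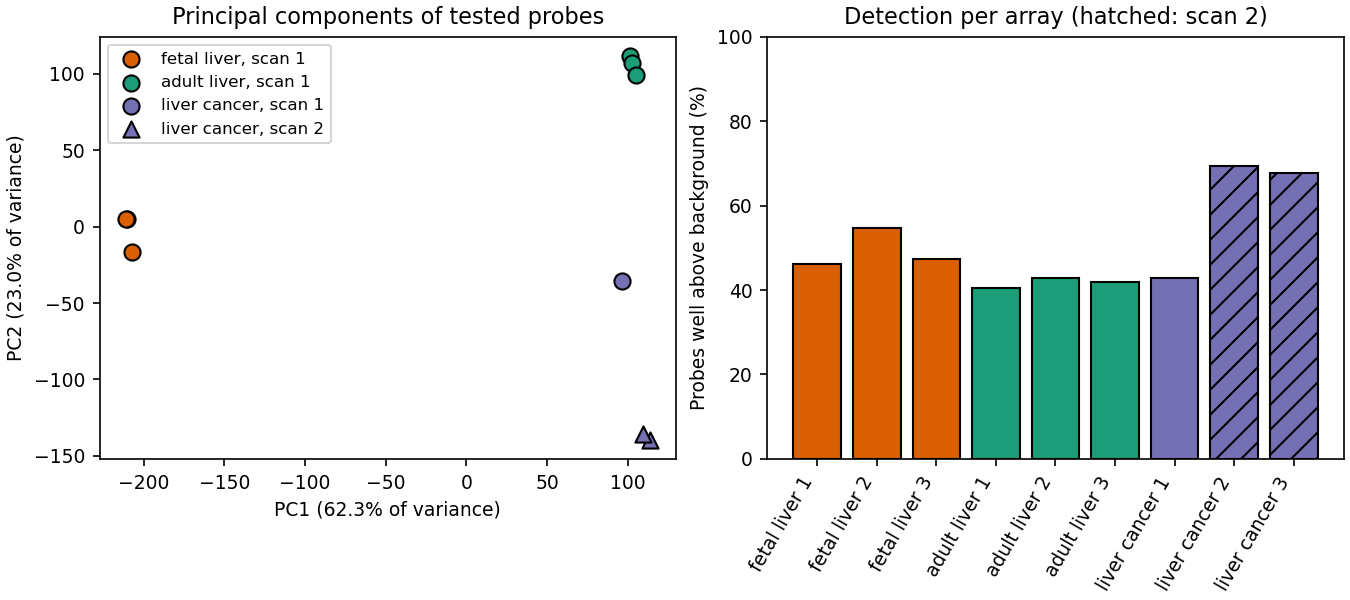
Left, first and second principal components of the tested probes, 1 point per array, coloured by group, with triangles for the second scan. Right, percent of probes well above background on each array: the hatched bars of liver cancer replicates 2 and 3 reach 69.3% and 67.8%, and no other array passes 54.8%.

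Fetal liver was set against adult liver to find transcripts of the developing organ. Of the 15 named genes, 7 were higher and 3 lower in fetal liver. Tuba1b, an alpha-tubulin of the cytoskeleton, was 9.88-fold higher (log2 fold change 3.31 ± 0.41 (SE, n = 3 per group), limma adjusted p = 0.00015). Tfrc, the transferrin receptor through which cells take up iron, was 7.94-fold higher (2.99 ± 0.26, limma adjusted p = 1.55e-05). Gk, glycerol kinase, which prepares glycerol for use in lipid and glucose synthesis, was lower (log2 fold change -3.45 ± 0.19, limma adjusted p = 6.92e-07). B2m, the light chain of class I antigen-presenting molecules, was 3.12-fold lower (-1.64 ± 0.25, limma adjusted p = 0.000495).

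The other genes higher in fetal liver were G6pd2, related to the first enzyme of the pentose phosphate pathway (2.53 ± 0.17), the ribosomal protein gene Rpl13a (1.93 ± 0.25), cytoplasmic actin Actb (1.54 ± 0.31), the TATA-binding protein gene Tbp (1.19 ± 0.33) and the chaperone gene Hsp90ab1 (1.09 ± 0.34). Ldhal6b, a lactate dehydrogenase-like gene, was lower (-2.37 ± 0.48). Levels of all 10 genes lay apart between the groups on every array. For instance, Tfrc stood at 9.74 ± 0.05 (SD, n = 3) in fetal liver and 6.75 ± 0.04 in adult liver, in log2 units relative to each array's 75th percentile. Nono, a nuclear RNA-binding protein gene, reached 1.05 ± 0.43 without passing the adjusted threshold (limma adjusted p = 0.0692), though it passed within the first scan. Hprt, Gusb, Ppia and Gapdh did not pass, at 0.39, 0.15, -0.10 and -0.36. The call of Hsp90ab1 was lost on leaving out any 1 fetal or adult array (1.04 to 1.17), and that of Tbp without fetal liver replicate 1 (1.15) or 3 (1.13). The spread in these fits takes in the more variable liver cancer arrays. Within the first scan the same differences had an SE of 0.12 for Hsp90ab1 and 0.14 for Tbp, against 0.34 and 0.33 over all arrays. With normexp background correction Ldhal6b was not called (-0.78), and Gk and G6pd2 were at -2.15 and 1.65. Scaling to the array median ended the calls of Hsp90ab1 (1.04) and Tbp (1.13), and the signs of Ppia (0.45) and Gapdh (0.18) flipped under quantile normalization. G6pd2, Ldhal6b, Tuba1b, Actb, Gapdh, Ppia, Rpl13a and Hsp90ab1 belong to families with near-identical copies, and signal shared with such copies was not separated, so these genes are uncertain.

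**Figure D2:**
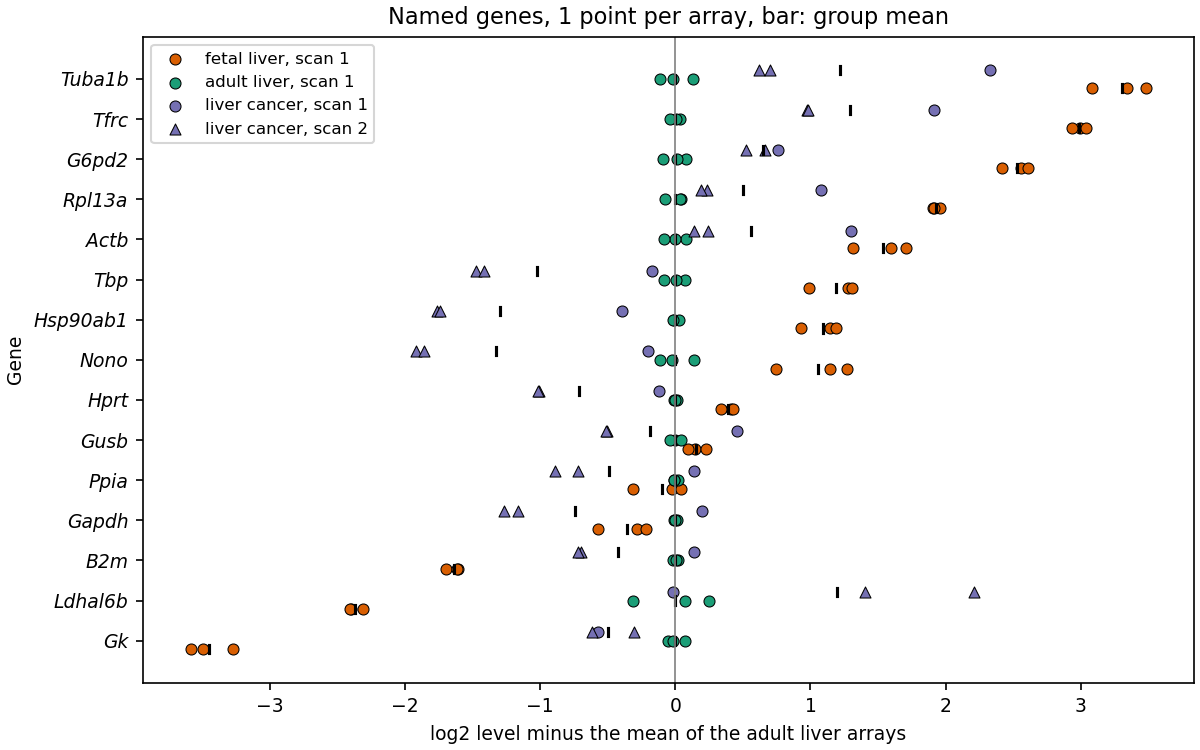
log2 level of each named gene on each array minus the mean of the adult liver arrays, ordered by the fetal difference, with triangles for the second scan and black bars for group means. Tuba1b (3.31) and Tfrc (2.99) lie highest in fetal liver and Gk (-3.45) lowest, and liver cancer replicates 2 and 3 both lie below replicate 1 for 13 of the 15 genes.

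Across all tested probes, 13489 were called between fetal and adult liver, 7222 higher and 6267 lower, by limma at an adjusted p below 0.05 and a fold change of at least 2. Of these, 3451 were at least 4-fold higher and 3106 at least 4-fold lower. The 2 groups did not overlap on 66.1% of probes, where chance gives 10%. All 6 arrays belong to the first scan, and within that scan 13986 probes were called. The count was 7189 among probes above background on all 9 arrays and 5949 with normexp background correction.

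Among the 519 lincRNA-named probes, 20 were higher and 99 lower in fetal liver, against 6 and 17 with normexp. The strongest rise was that of humanlincRNA0970-_P1 (4.94 ± 0.49, limma adjusted p = 3.48e-05), followed by humanlincRNA1151+_P1 (3.78 ± 0.18). The strongest falls were those of humanlincRNA1249-_P1 and humanlincRNA0323+_P1 (-4.06 ± 0.33). The former was not well above background on any fetal array and was at least 5.67-fold lower on processed signals. It was at -2.50 with signals floored, and at -0.91, without a call, with normexp background correction. Without adult liver replicate 2 it measured -4.83, against -4.06 over all arrays. With normexp humanlincRNA0323+_P1 was at -1.50, humanlincRNA0970-_P1 at 3.43 and humanlincRNA1151+_P1 at 1.93. What the lincRNA names stand for is not given in the sources used here.

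Liver cancer was set against adult liver to find transcripts of the tumour. Of the 15 named genes, 1 was higher and 3 lower. Tfrc was 2.45-fold higher (1.29 ± 0.26 (SE, n = 3 per group), limma adjusted p = 0.006), at 8.67, 7.73 and 7.73 on the liver cancer arrays against 6.75 ± 0.04 (SD, n = 3) in adult liver. Within the first scan its difference was 1.92 ± 0.15, also past the threshold. Without liver cancer replicate 1 it was 0.98, under the minimum fold. Scaling to the array median left it at 1.01 without a call.

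Nono (-1.33 ± 0.43), Hsp90ab1 (-1.30 ± 0.34) and Tbp (-1.02 ± 0.33) were lower in liver cancer by limma over all 9 arrays. None of these 3 calls held within the first scan, where the differences were -0.20, -0.40 and -0.17. A block for scan adds no further evidence on these differences, since it rests on liver cancer replicate 1 alone. Each was also lost without liver cancer replicate 2 or 3 and without any 1 adult array, with differences of -1.38 to -0.79. With normexp they lay at -0.76, -0.74 and -0.56, under the minimum fold. Of 22 alternatives other than thresholds, 13 ended the call of Nono, 9 that of Hsp90ab1 and 14 that of Tbp. Conversely, Tuba1b (1.22 ± 0.41, limma adjusted p = 0.0524), Actb (0.56 ± 0.31) and Rpl13a (0.50 ± 0.25) did not pass over all arrays. Within the first scan they passed as higher in liver cancer, at 2.33 ± 0.21, 1.30 ± 0.20 and 1.08 ± 0.15. G6pd2 lay at 0.65 ± 0.17, under the minimum fold, and at 0.76 within the first scan. Gk lay at -0.50 ± 0.19 and B2m at -0.43 ± 0.25, neither past the threshold, and within the first scan at -0.57 and 0.14. B2m was at 0.01 under quantile normalization, as was Gk with normexp background correction. Ldhal6b (1.20), Hprt (-0.72), Gapdh (-0.75), Ppia (-0.49) and Gusb (-0.19) did not pass either. In the first scan they lay at -0.02, -0.12, 0.20, 0.14 and 0.46, also without passing. With normexp Ppia (0.09) and Gusb (0.37) changed sign.

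Over all tested probes 8205 were called between liver cancer and adult liver, 3958 higher and 4247 lower, of which 1274 were at least 4-fold higher and 1279 at least 4-fold lower. The groups did not overlap on 42.6% of probes, where chance gives 10%. Scaling to the array median in place of the 75th percentile gave 2782 higher and 5627 lower, and moved the median fold change of all tested probes from 0.01 to -0.27. With scan as a block 6250 probes were called, and within the first scan 6176, of which 3025 were higher and 3151 lower. Of the 3958 probes called higher over all arrays, 2063 (52.1%) were also called higher within the first scan, and of the 4247 called lower, 2522 (59.4%) were also called lower. A lost call does not show that the change was absent: the median differences were 1.63 and -1.62 over all arrays and 1.39 and -1.32 within the first scan, whose liver cancer array also took part in the calls. Without liver cancer replicate 1, 12117 probes were called.

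Of the lincRNA-named probes, 48 were higher and 33 lower in liver cancer than in adult liver. Within the first scan more were lower than higher. On liver cancer replicates 2 and 3, 46.6% and 42.7% of lincRNA-named probes were well above background, against 18.6% to 26.8% on the other arrays. In the dimmest of 10 equal classes of the tested probes by mean level, the median difference from adult liver was 0.49 log2 on these replicates. It was -0.12 on replicate 1. Whether the second scan raised the number called higher was not tested. The probe humanlincRNA0111+_P1 rose most (4.42 ± 0.23, limma adjusted p = 4.42e-06; 4.84 within the first scan). Next was mouselincRNA1040+_P1 (3.96 ± 1.08), which was not called within the first scan (1.06) and lost its call without adult replicate 1 or 2 or liver cancer replicate 2 (3.32) or 3 (3.14), and was at 5.40 without liver cancer replicate 1. The lowest were humanlincRNA1627+_P1 (-3.53 ± 0.91) and humanlincRNA0219+_P1 (-3.31 ± 0.66), at -1.96 and -1.98 within the first scan. With scan as a block neither was called, and the former lost its call without adult liver replicate 1. They lay at -4.32 and -3.97 without liver cancer replicate 1, and at -2.34 and -2.45 without replicate 2. With normexp mouselincRNA1040+_P1 was at 2.27, humanlincRNA1627+_P1 at -1.94 and humanlincRNA0219+_P1 at -2.11. In total, 50 lincRNA-named probes passed with scan as a block and 54 within the first scan. Without liver cancer replicate 1 the total was 146. It was 51 without adult liver replicate 1, and 52 and 53 without liver cancer replicates 2 and 3.

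Liver cancer was also set directly against fetal liver. Of the named genes, 3 were higher in liver cancer and 8 lower. Gk was 7.76-fold higher in liver cancer (2.96 ± 0.19 (SE, n = 3 per group), limma adjusted p = 1.9e-06), and B2m was 2.32-fold higher (1.21 ± 0.25, limma adjusted p = 0.00283). Within the first scan they lay at 2.88 and 1.78, both past the threshold, while B2m fell short of the minimum fold without liver cancer replicate 1 (0.93) and when scaled to the array median (0.99). With normexp Gk and B2m were at 2.15 and 1.84. Ldhal6b was higher as well (3.57 ± 0.48; 2.35 within the first scan and 4.18 without liver cancer replicate 1), at 1.84 with normexp. Tfrc was 3.24-fold lower in liver cancer (-1.70 ± 0.26, limma adjusted p = 0.000552; -1.07 within the first scan).

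G6pd2, Nono, Hsp90ab1 and Tbp were lower in liver cancer than in fetal liver (-1.88, -2.38, -2.39 and -2.21) and remained past the threshold within the first scan (-1.77, -1.25, -1.49 and -1.36). Tuba1b (-2.09 ± 0.41), Rpl13a (-1.43 ± 0.25) and Hprt (-1.11 ± 0.26) were lower over all arrays but missed the minimum fold within the first scan, at -0.97, -0.85 and -0.51. Hprt also missed it without liver cancer replicate 2 or 3 (-0.96 in each case). Under normexp Rpl13a (-0.79) and Hprt (-0.56) lost their calls, and G6pd2, Nono, Tbp and Tuba1b were at -1.24, -1.75, -1.59 and -1.47. Actb (-0.98), Ppia (-0.39), Gapdh (-0.39) and Gusb (-0.34) were not called. In the first scan they lay at -0.24, 0.24, 0.55 and 0.30, again without a call, and with normexp at -0.35, 0.25, 0.23 and 0.24. Tfrc and G6pd2 in liver cancer thus lay below fetal liver by a tested difference, and Tfrc also lay above adult liver.

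In this comparison 14462 probes were called, 6950 higher and 7512 lower in liver cancer. The groups showed no overlap on 58.3% of probes, where chance gives 10%. Array-median scaling gave 5695 higher and 8704 lower, and leaving out the filter on dim probes gave 9524 higher and 8056 lower. The count was 13144 with scan as a block and 13089 within the first scan. Of the lincRNA-named probes, 115 were higher and 19 lower in liver cancer. The total of 134 compares with 97 with scan as a block and 94 within the first scan. The largest rise was that of mouselincRNA1468-_P1, not well above background on any fetal array and at least 24-fold higher in liver cancer (measured means 1.74 ± 0.09 and -4.13 ± 0.08 (SD, n = 3), limma adjusted p = 6.91e-08). In the first scan it was at least 25.7-fold higher. With normexp its difference over all arrays was 2.27 log2, against 4.58 with signals floored. Next was mouselincRNA1040+_P1, below background on every fetal array and variable in liver cancer (1.27 ± 2.52). From the liver cancer mean it was at least 17.3-fold higher, but within the first scan at least 2.32-fold. With normexp its difference over all arrays was 2.44 log2, against 4.11 with signals floored. Without liver cancer replicate 1 the measured difference was 7.04, and without replicates 2 and 3 it was 4.96 and 4.77, against 5.59 over all arrays. The largest falls were those of humanlincRNA0970-_P1 (-4.55 ± 0.49) and mouselincRNA1103-_P1 (-3.73 ± 0.42), at -5.64 and -3.01 within the first scan and -3.18 and -2.70 with normexp.

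**Figure D3:**
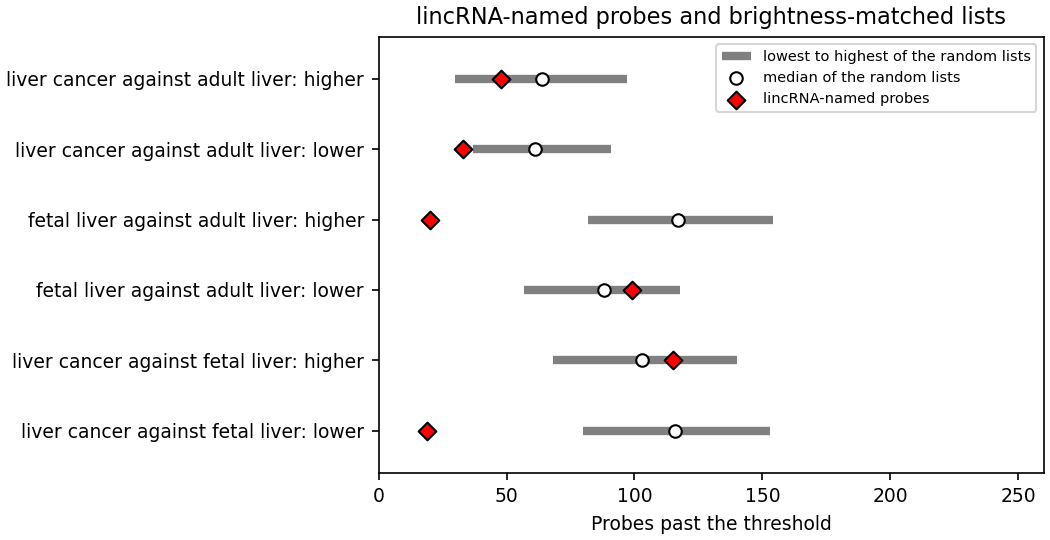
Number of the 519 lincRNA-named probes past the threshold in each comparison and direction (red), with the range and median of 10000 random lists of other probes matched on mean brightness (grey bar and white circle). In fetal against adult liver 20 were higher, and the lowest of the random lists had 82. The lists were not matched on which arrays were above background.

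The oncofetal set comprised the probes higher in both fetal liver and liver cancer than in adult liver. Among named genes it held Tfrc alone over all arrays (2.99 in fetal liver and 1.29 in liver cancer). Within the first scan Tuba1b, Actb and Rpl13a were also higher in both. The set held 1503 probes, 20.8% of those higher in fetal liver and 38.0% of those higher in liver cancer, and 4 of them had lincRNA names. Of these the largest rise was that of humanlincRNA0111+_P1 (4.42 in liver cancer and 2.58 ± 0.23 in fetal liver, the latter at 1.97 with normexp). The next, humanlincRNA2282-_P1, was not well above background on any adult array and was at least 1.78-fold higher in liver cancer and at least 1.37-fold higher in fetal liver. Of the other 2 lincRNA-named probes, 1 showed no rise once its adult signals were raised to the background level, and 1 was not called in liver cancer within the first scan. The calls of humanlincRNA2282-_P1 were lost when signals were floored at the background level, where its differences equal these bounds, and with normexp, which put them lower (0.02 and 0.27), so no rise is shown for it. With scan as a block 1331 probes were higher in both, and within the first scan 1304. The set was smaller with signals floored (819), with treat against a 1.5-fold change (730), among probes above background on all 9 arrays (559) and with normexp (488). The 1503 probes had a median log2 difference from adult liver of 1.62 over all liver cancer arrays and 1.54 within the first scan, and 931 of them (61.9%) were also called higher in liver cancer within the first scan, 930 of them in both comparisons.

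The set lower in both fetal liver and liver cancer held 2033 probes, 26 of them with lincRNA names and none of the named genes. It included humanlincRNA1627+_P1, at -3.53 in liver cancer and, being below background on every fetal array, at least 10.2-fold lower in fetal liver. Its call in fetal liver was lost with normexp (-1.19, against -3.35 with signals floored). Its call in liver cancer was lost within the first scan (-1.96) and without adult liver replicate 1. It also included mouselincRNA1636+_P1 (-3.04 ± 0.25 and -2.93 ± 0.25), with the difference in liver cancer at -3.05 within the first scan and both falls smaller with normexp (-1.57 in fetal liver). With scan as a block the set held 1544 probes and within the first scan 1557. A further 688 probes were higher in fetal liver and lower in liver cancer, and 521 were lower in fetal liver and higher in liver cancer. Relative to both other groups, 5308 probes were higher in fetal liver and 1980 higher in liver cancer.

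Fetal liver and liver cancer were compared with the same adult arrays, so part of any overlap is expected without an effect. In 20 simulations of unchanged groups, at most 1 probe was called higher in both and at most 1 lower in both. Few probes are called at all in unchanged groups, so these counts cannot tell shared changes from unrelated changes measured against the same adult arrays. Independent lists of the observed lengths would share 838 probes higher in both and 780 lower in both, and would place 899 and 727 probes in the opposed sets, where 688 and 521 were found. Across probes, which are not independent replicates, the fold changes correlated at r = 0.316 (rho = 0.253), against 0.407 for simulated unchanged groups, and at 0.302 within the first scan. The simulated r reflects spread between arrays alone, so it is no reference for probes that changed. The covariance of the fold changes was 0.683 against 0.0620 in the simulations, a difference of 0.621. Random spread of the shared adult arrays gave at most 0.0637 in the simulations. With 3 adult arrays the controls could not be divided into 2 sets of at least 2. A departure common to all 3 adult arrays was not simulated and may account for part of the excess.

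**Figure D4:**
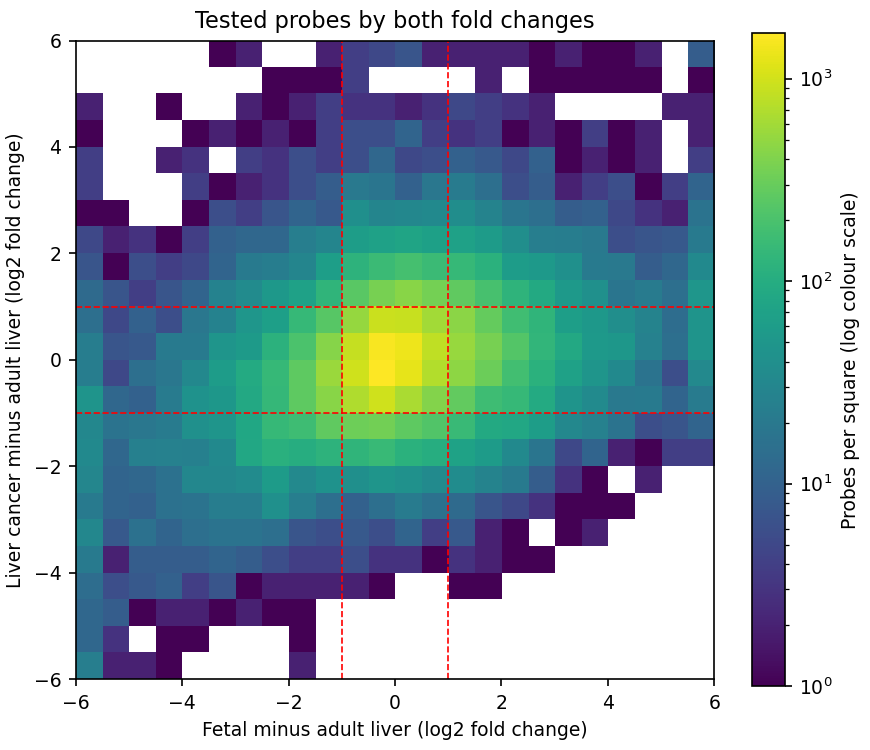
Tested probes by log2 fold change of fetal liver (horizontal) and of liver cancer (vertical) against adult liver, in squares of 0.5 with a logarithmic colour scale; values beyond 6 are drawn in the outermost squares, and dashed lines mark a fold change of 2. The 1503 probes called higher in both lie in the upper right corner and the 2033 called lower in both in the lower left. These corners also hold probes that did not pass the adjusted p threshold in both comparisons.

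**Figure D5:**
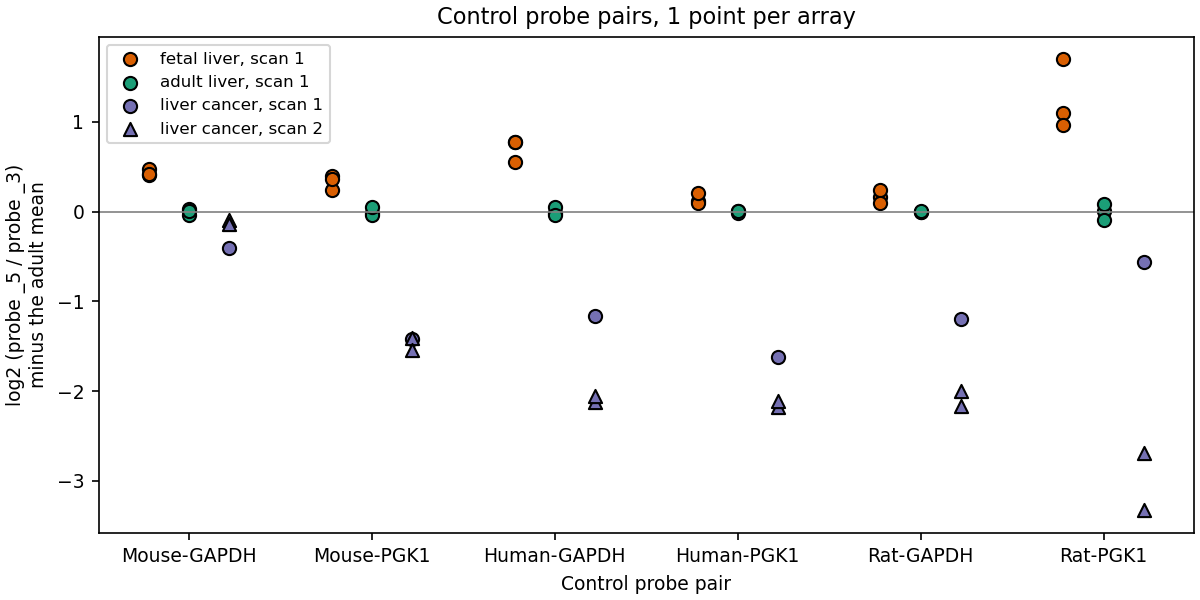
Difference between the control probes ending in 5 and in 3 of each pair, minus the mean of the adult arrays, 1 point per array, with triangles for the second scan. In the 5 pairs with both probes above background on every array, the 3 liver cancer arrays lie below the 6 others and the fetal arrays above the adult ones; Rat-PGK1 is not measured reliably.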

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

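The tests of the ERCC-named controls and all tests of the control probe pairs were chosen after the result was seen; the other tests here were set before.

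Probes higher in both fetal liver and liver cancer than in adult liver numbered 1503. Of 100 splits drawn from the 840 ways to form 3 groups of 3 arrays, 3 gave as many, the real one included, a share under 0.05. The median of the other splits was 0, since mixing unlike groups widens the spread within a group. The splits therefore cannot exclude a chance overlap of the fetal and liver cancer lists. The highest other split gave 3769, with the 3 fetal arrays as the low group and adult and liver cancer arrays mixed, which points to the distance of the fetal arrays from all others. For the counts of the single comparisons, the 10 splits of 6 arrays are too few for a share under 0.05. In each case 1 split, the real one, gave as many, with 8205, 13489 and 14462 probes by limma for liver cancer against adult liver, fetal against adult liver and liver cancer against fetal liver. The highest other split gave 0, and at an unadjusted p under 0.05 it gave at most 5837, 600 and 4493.

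Dimmer adult arrays were argued against as the whole cause of the set higher in both by the bound set before: under quantile normalization the count was 93.3% of its value. The main values were already scaled to each array's 75th percentile, so this rescaling says little about signals near background. The count was 1074 with array-median scaling, 819 with signals floored, 559 with probes above background on all arrays and 488 with normexp. Dim signals may thus account for part. The scan of liver cancer replicates 2 and 3 was argued against as the whole cause too. Over 2045 probes called higher in both without replicate 1, that replicate lay above the adult mean by a median of 1.02 log2 (quartiles 0.30 and 1.89), against 1.76 on replicates 2 and 3. The adult arrays enter both the choice of these probes and the difference. Red blood cell precursors and dividing cells in both tissues stay open, since the erythroid list had 1 named gene, Tfrc, and the cell cycle list 0. Age, DEN exposure and tumour tissue stay open as well, untested against each other.

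Signals in control probes set liver cancer replicates 2 and 3 apart. ERCC-named control spots, which target no mouse gene, were well above background for 51.2% and 44.8% on these arrays against 8.57% to 11.7% on the other 7. Negative control spots were above background for 7.0% and 3.33%, against 0% to 1% elsewhere. Spots named as bright corner controls had a median signal of 118240 and 117920, against 10774 to 21437 on the other 7 arrays. Replicate 1 differed from the mean of replicates 2 and 3 by at least 1 log2 on 9902 probes, and replicates 2 and 3 from each other on 3788.

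An adult liver of 2 months in place of a tumour was argued against for replicate 1. It lay beyond all 3 adult arrays on the tumour side for 61.3% of 23129 probes that separated replicates 2 and 3 from them. Chance gives 25% on unselected probes, which is no reference here. These probes were chosen because replicates 2 and 3 lay beyond the same adult arrays, so chance gives a far higher share. That share was not computed, and 61.3% by itself is weak evidence. The argument rests more on correlation: replicate 1 correlated at 0.924 to 0.925 with the adult arrays of its scan, which correlated at 0.978 with each other. Its correlations with replicates 2 and 3 were 0.931 and 0.934. Liver outside a tumour from 1-year mice given DEN was not measured. The bright corner spots show a technical difference between the arrays of the 2 scans. How much of the distance of replicate 1 comes from scan and slide stays open and was not tested. The shares of ERCC-named spots, 44.8% or more, lay above the first scan, but they prompted this explanation and lend it no independent support. Differences between tumours cannot be told apart from the scan, because 0 arrays of another group share the second scan.

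Control probes in pairs named for Gapdh and Pgk1 also differed between groups. The probe ending in 5 minus that ending in 3 changed between adult liver and liver cancer by -0.21 for Mouse-GAPDH, -1.45 for Mouse-PGK1, -1.78 for Human-GAPDH, -1.97 for Human-PGK1 and -1.79 for Rat-GAPDH (log2, 3 arrays per group). Each had an exact permutation p of 0.1, two-sided, the smallest this design can give. The computed -2.19 for Rat-PGK1 is no measurement, since its probe ending in 3 was mostly not above background in the first scan. In the 5 other pairs the 3 liver cancer arrays lay below the 6 others. The largest shifts came from pairs named for human and rat, although the RNA was from mouse. How such probes read mouse transcripts was not tested, and pairs named for the same gene are not independent. The measure also differed in the other direction between fetal and adult liver: in these 5 pairs the fetal arrays lay above the adult ones, all within the first scan, by 0.44, 0.33, 0.70, 0.14 and 0.16 in the same order, each with an exact permutation p of 0.1, two-sided. Reading the endings as the 5' and 3' ends of a transcript is an assumption, since the labels do not explain them.

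The scan and slide were argued against as the whole cause for these 5 pairs, in which liver cancer replicate 1, from the first scan, showed over 50% of the mean shift of replicates 2 and 3. The share was 96.2% for Mouse-PGK1, 75.9% for Human-PGK1, 57.5% for Rat-GAPDH, 55.8% for Human-GAPDH and 359% for Mouse-GAPDH, whose shift was small, so the scan stays open for the rest of the shift. For Rat-PGK1 the share was 18.5%, which decides nothing, so the scan stays open for this pair.

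A lower level of the gene itself would move both probes alike. The difference of -1.45 argues against it as the whole cause for Mouse-PGK1, but for Mouse-GAPDH the probes changed by -0.70 and -0.91, and the difference of -0.21 leaves it open. On replicate 1 alone, scanned with the adult arrays, they changed by 0.21 and -0.20, so the fall of both rests on the second scan. Shorter labelled RNA in the tumours stays open and untested: that the probe ending in 5 moved down in the 5 measured pairs, named for 2 genes only, restates the pattern (6 pairs as computed, with Rat-PGK1, which was not measured). A biological difference in transcript ends was not tested.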

How the results depend on the processing

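The normexp correction and the fits within the first scan were chosen after the data were seen; the other alternatives were set before.

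Requiring signal above background on all 9 arrays leaves fewer probes to test. It gave 1734 higher and 2824 lower for liver cancer against adult liver, 3287 and 3902 for fetal against adult liver, and 3790 and 4056 for liver cancer against fetal liver. It gave 559 higher in both, 1331 lower in both, and 35, 58 and 63 lincRNA-named probes in the comparisons in the same order. Treat, which tests against a 1.5-fold change, gave 1955 higher and 2427 lower in liver cancer than in adult liver, 730 higher in both, 1259 lower in both, and 33, 79 and 85 lincRNA-named probes. With normexp 2899 were higher and 3050 lower in fetal than adult liver, 4526 higher in liver cancer than in fetal liver, 488 higher in both and 895 lower in both. LincRNA-named calls were then 23 in fetal against adult liver and 62 in liver cancer against fetal liver, and the correlation of fold changes was 0.181. With signals floored 819 were higher in both and the correlation was 0.264.

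Of lincRNA-named probes in liver cancer against adult liver, 81 were called, against 154 with array weights and 50 with scan as a block. Leaving out single arrays gave 51 (without adult liver replicate 1) to 146 (without liver cancer replicate 1), with 52 and 53 without liver cancer replicates 2 and 3. Without a filter on dim probes 231 were called in liver cancer against fetal liver. Except where the number tested or the threshold differs, the cause was not tested.

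Replicate number as a block gave 4071 higher and 4368 lower in liver cancer than in adult liver and 1517 higher in both. Correlations of same-numbered arrays ran from -0.16 to 0.31, so the numbers do not pair the arrays.

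Array-median scaling moved the median fold change of tested probes to -0.27 for liver cancer against adult liver and to -0.18 against fetal liver, and normexp to -0.27 and -0.26. For called named genes, call and direction held in 208 of the cases tried for fetal against adult liver, with the call lost in 12. The figures were 50 and 38 for liver cancer against adult liver and 229 and 13 against fetal liver. For named lincRNA probes they were 370 and 17, and in these cases 0 directions reversed. Gene set tests and the probe of a gene were not run, for lack of gene names.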

Other observations

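The tests of matched lists, of paired names and of brightness were all chosen after the data were seen.

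LincRNA-named probes were called less often than matched probes in several comparisons, most of all as higher in fetal liver. Of 519 tested, 20 were called higher than in adult liver, where 10000 random lists of other probes matched on brightness had a median of 117 (82 to 154) and 0 lists had as few. The count was 21 against a median of 115 under quantile normalization, 20 against 112 under array-median scaling, 13 against 78 with signals floored and 6 against 34 with normexp. The 99 called lower in fetal than in adult liver lay within the range of matched lists (median 88, 57 to 118). So did the 115 called higher in liver cancer than in fetal liver (median 103, 68 to 140). With normexp, however, 17 were lower in fetal than in adult liver against a median of 30, and 40 lists had as few. In liver cancer against adult liver 33 were lower against a median of 61 (37 to 91), with 0 lists as low, and 48 were higher against 64, with 145 lists as low. Within the first scan these were 32 against 49 and 22 against 45. Against fetal liver, 19 were lower in liver cancer, where matched lists had a median of 116 (80 to 153), and within the first scan 19 against 112. The lists were matched on the mean over all 9 arrays, not on which arrays were above background. Of lincRNA-named probes on the array, 46.6% and 42.7% were above background on liver cancer replicates 2 and 3, against 18.6% to 26.8% elsewhere. Probes tested because of those arrays may be unlikely to be called higher in fetal liver, so the deficit cannot be credited to lincRNA names. Other settings used the same tested probes and lists, so they are no separate support.

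Of lincRNA names, 876 occurred with both a plus and a minus sign. Both members were above background on all 3 arrays for 34 names in fetal liver, 27 in adult liver and 34 in liver cancer, where independence would give 25.2, 20.8 and 30.7. The plus member alone was above background for 114, 113 and 126 names, and the minus member alone for 115, 103 and 134. Over 74 pairs with both members tested, which are probes and not independent replicates, fold changes of the members correlated at r = 0.131 for fetal against adult liver, 0.161 for liver cancer against adult liver and 0.0447 for liver cancer against fetal liver.

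The difference between liver cancer replicates 2 and 3 and replicate 1 varied with brightness. In 10 equal classes of the tested probes by mean level, its median ran from 0.36 log2 in the dimmest to -0.75 in the brightest. The median of replicate 1 minus adult liver was -0.12 in the dimmest and 0.28 in the brightest class.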
